A study of Brassica rapa with 12 samples.

How the data were processed

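RNA from stems and buds of 8-week-old wild type and BrCHR39-silenced Brassica rapa was extracted with Trizol and made into Illumina libraries, per the labels' protocols. Whether the kit kept strand, and whether reads were paired, is not given in the sources used here. The 12 libraries were grouped by the tissue and genotype in their titles, with 3 libraries per group, and all columns of both deposited tables matched a sample title.

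The deposited count table holds whole numbers of reads per gene for 41020 genes, not normalized. The submitters' processing notes name HISAT2 2.1.0, Bowtie 1.0.1, TopHat2 and featureCounts 2.0.1, without their roles; the genome build and annotation are not given in the sources used here. The deposited FPKM table was made by the authors from the same counts. It lists 36230 genes, and the 4790 left out had 0 reads in every library, as had 579 of those listed. Each FPKM value equalled the count divided by the library total and by a gene length: the length came out whole, within a relative tolerance of 1e-06, in all 35651 genes with reads. All lengths were multiples of 3, with a median of 1041 bases, so they are coding lengths and hold no untranslated regions. Reads assigned to genes ranged from 12275190 to 15693349 per library. A gene with 0 reads in a library could lie at up to 0.191 to 0.244 CPM (3 reads of the total); such floors cover counting error only.

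No genome was used here, and no coordinates are given. The gene table provided (CAAS_Brap_v3.01 assembly) paired 1 of the 41020 identifiers with a name. The 38 gene lists planned, among them hormone pathways, bud dormancy, floral and pollen markers and chromatin remodellers, could therefore not be matched to genes and were not tested, and neither were markers of other cell types. The level of BrCHR39 was not analysed here for the same reason. Genes with near-identical copies are common in this genome, and reads shared between copies could be split or lost in the authors' counting.

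Tests used the raw counts in edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr with its minimum count of 10, which left 28114 and removed 12906. Libraries were scaled by TMM, and the quasi-likelihood test was fitted to all 12 libraries with 1 term per group. The common biological coefficient of variation was 2.89%. Calls have a Benjamini-Hochberg adjusted p under 0.05, two-sided. The comparisons were silenced against wild type in stem and in bud, the difference of these effects (interaction), and bud against stem in wild type. CPM values use the TMM library sizes. A fold against a group with 0 reads is a lower limit that sets the group at 3 reads over its 3 libraries. The genes named were chosen by a rule written before the data were examined: with no names for the identifiers, at most 2 per direction and comparison, those with the largest fitted change among called genes whose groups did not overlap and whose higher group averaged at least 5 CPM. Tissue-restricted genes were a class added after the data were seen. Classes taken from the wild type bud against stem calls were tried first and dropped, because they share libraries with the silencing effects, and bins of a tissue effect averaged over genotypes were tried next and showed little trend. The limits kept use the mean over both genotypes, so that picking the class does not favour either direction. Gene sets were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2, with the preset correlation of 0.01 and with an estimated one.

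The scripts were tested on simulated counts drawn from the real means and library sizes with 200 changed genes in the stem comparison (27472 genes). There the test recovered 18 of 50 genes changed 1.2-fold, 37 of 50 changed 1.5-fold, 42 of 50 changed 2-fold and 49 of 50 changed 4-fold, with 7 false calls. In a bud comparison simulated without any effect there were 0 calls, and bud-restricted genes split into 561 below and 560 above 0. In the data 69.7% of the genes were called in stem and 79.8% in bud. The simulation therefore does not test the scaling where most genes change.

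The alternatives were DESeq2's size factors, no low-count filter, DESeq2 1.42.0, fits of the compared groups alone, the replicate number as a block, a minimum change of 2-fold, limma on log2(FPKM + 1) and log2(FPKM + 0.1) for 27487 genes with at least 1 FPKM in 3 libraries, and leaving out each library. Added after the data were seen were library totals alone and upper-quartile scaling in place of TMM, a test against 1.5-fold, other class limits and another read minimum.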

Results

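Messenger RNA was sequenced from stems and buds of 8-week-old Brassica rapa, the crop species that includes Chinese cabbage and turnip. The plants were wild type or transgenic lines in which BrCHR39 had been silenced. The series presents BrCHR39 as an ATPase that remodels chromatin and promotes apical dominance, the suppression of side shoots by the growing shoot tip. The 12 libraries formed 4 groups of 3, namely wild type stem, silenced stem, wild type bud and silenced bud. Between 12275190 and 15693349 reads per library were assigned to genes, and 28114 of the 41020 listed genes carried enough reads to be tested. The genes are listed by identifier only, so at most 2 identifiers are printed per direction in each comparison. BrCHR39 itself could not be looked up by name, and the level of the silenced gene was therefore not analysed here.

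Tissue separated the libraries most, followed by genotype within each tissue. The first principal component held 63.9% of the variance of log2 CPM (read counts scaled to library size) and parted stems from buds. The next 2 components held 19.6% and 13.5%. The former mainly set wild type buds opposite silenced buds, and parted the stems less widely, with the genotypes in the reverse order. The latter mainly set wild type stems opposite silenced stems, and parted the buds less widely, with the genotypes in the same order. Libraries of the same group correlated at 0.990 to 0.992 across genes. Wild type and silenced stems correlated at 0.892 to 0.893, and wild type and silenced buds at 0.838 to 0.841. Wild type stems correlated with wild type buds at 0.651 to 0.653, and silenced stems with silenced buds at 0.693 to 0.695. Across genotypes, silenced stems correlated with wild type buds at 0.702 to 0.704, and wild type stems with silenced buds at 0.676. Stems of each genotype were thus closer to buds of the other genotype than to buds of their own. The genotype labels could not be checked on the level of BrCHR39. These correlations run across genes, which are not independent replicates. The 3 libraries of a group lay close together: genes with over 2000 reads in a pair of libraries had a coefficient of variation of 2.99% to 3.48% between replicates. The variance between replicates was 1.55 to 1.69 times that of counting alone, against 112 to 118 times between genotypes in stem and 122 to 142 times in bud. Nothing in the labels says that the 3 libraries of a group came from separate plants, so all p-values measure only the spread between these libraries, which may be technical.

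**Figure D1:**
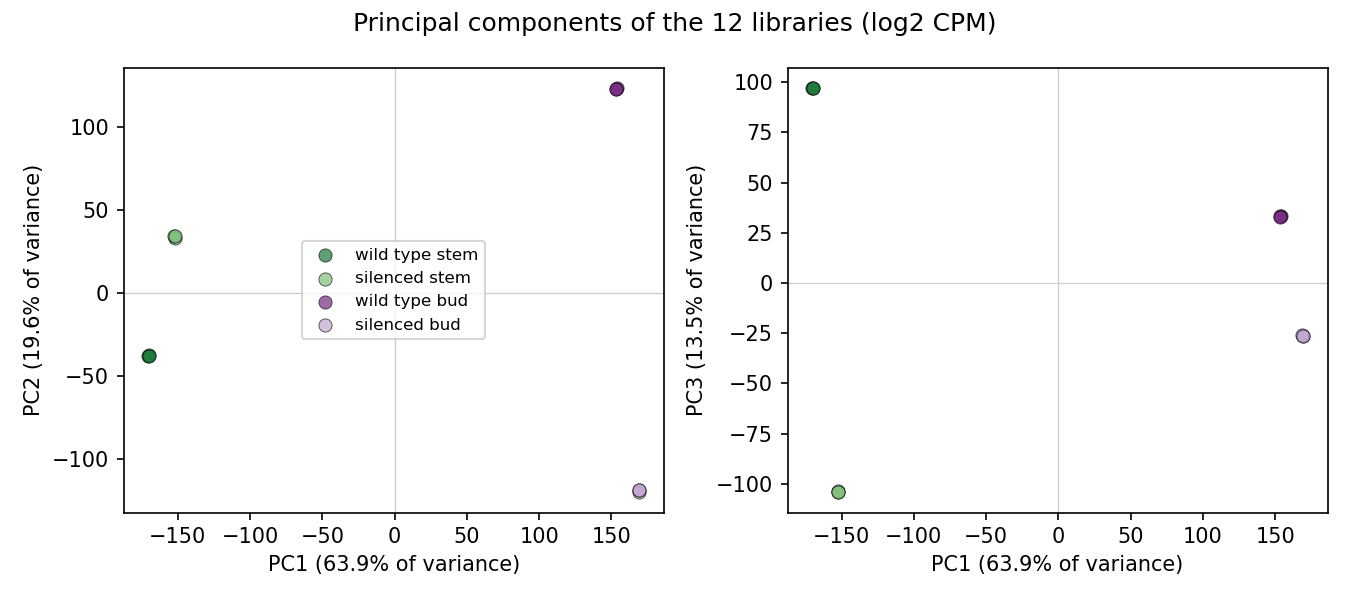
Principal components of log2 CPM over the 28114 tested genes, with 1 point per library and 3 per group. The axes give the component scores in log2 units and the share of the variance. The first component parts stems from buds and the next 2 part the genotypes, and the 3 libraries of each group overlap.

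The buds held reads from more genes than the stems, and silenced plants fewer than wild type plants in both tissues. Wild type buds had at least 1 read in 31761 ± 192 genes (SD, n = 3) and silenced buds in 29911 ± 65.8 genes. Wild type stems had reads in 29359 ± 62.3 genes and silenced stems in 28723 ± 35.8 genes. In both tissues every silenced library detected fewer genes than every wild type library; an exact permutation test of 3 against 3 libraries cannot go below p = 0.10, so none is given. Stem RNA was more concentrated: the 100 most abundant genes took 18.6% of the reads in wild type stems and 16.8% in silenced stems, against 10.4% in wild type buds and 11.5% in silenced buds. One identifier, Bra000116, matched a gene name, SWEET9, a sugar transporter of nectaries. It had 0 reads in all 12 libraries, which allows at most 0.244 CPM in the shallowest library and 0.191 CPM in the deepest.

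The first comparison asks which genes differ in stem when BrCHR39 is silenced. At least 2-fold changes were almost evenly split: 4061 genes rose and 4025 fell in silenced stems at an adjusted p under 0.05 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 3 libraries against 3). Shifting the fold changes of these calls to 3 other scalings left between 3814 and 3991 higher and between 4079 and 4218 lower. Changes of 8-fold or more leaned towards loss, with 1052 genes lower and 574 higher. The genes that fell furthest went from a clear signal to no reads. Bra034180, with a coding length of 1320 bases, stood at 143 ± 3.06 CPM (SD, n = 3) in wild type stems and had 0 reads in silenced stems, at least 1754-fold lower. Bra015874, with a coding length of 732 bases, stood at 104 ± 0.352 CPM in wild type stems and also had 0 reads in silenced stems, at least 1271-fold lower. It went to 0 reads in silenced buds too, from 18.1 ± 1.84 CPM in wild type buds, and is among 29 genes with at most 3 reads in each silenced tissue despite at least 100 in each wild type tissue. The strongest rises started from nothing. Bra024251, with a coding length of 309 bases, had 0 reads in wild type stems and 29.1 ± 3.25 CPM in silenced stems, at least 379-fold higher, and Bra005843, with a coding length of 1527 bases, had 0 reads and 25.5 ± 2.19 CPM, at least 332-fold higher. These limits set the group at 0 to 3 reads over its 3 libraries, and all 4 genes passed edgeR's test, the largest adjusted p being 5.73e-61.

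Genes restricted to stem were lowered more often than raised. This class was chosen after the data were examined. It held the 443 genes that stayed under 0.5 CPM in each of the 6 bud libraries and averaged at least 2 CPM over the 6 stem libraries of both genotypes. In silenced stems 189 of them, 42.7%, were called at least 2-fold lower and 105, 23.7%, at least 2-fold higher, while 66 were not called at any size. Among the other tested genes 13.9% were called at least 2-fold lower and 14.3% at least 2-fold higher. Those other genes included some with no reads in any stem library, which could not be called in stem. The summed level of the class went from 8822 ± 45.3 CPM in wild type stems to 5439 ± 48.8 CPM in silenced stems, a ratio of 0.617. As a set the class fell relative to the other genes (limma's camera, adjusted p = 0.00138 with the preset correlation and adjusted p = 7.63e-05 with an estimated correlation, 2 classes tested). The adjustment does not count the classes and bins tried before on the same data, of which the bins showed little trend. The estimated correlation was -6e-04. It rests on the spread between replicate libraries, which may be technical.

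Counting changes of any size, 19598 of the 28114 genes, 69.7%, were called in stem, 10578 higher and 9020 lower; a fit of the 6 stem libraries alone called 9109 higher and 9523 lower. Of the calls, 11512 were changes of less than 2-fold, which the small spread between replicate libraries let pass the test.

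The second comparison asks the same question in bud, where losses prevailed. In silenced buds 6683 genes were called at least 2-fold lower and 3775 at least 2-fold higher, 1.77 times as many. Of the genes changed 8-fold or more, 2211 were lower and 260 higher. Bra020643, with a coding length of 2484 bases, stood at 274 ± 14.2 CPM (SD, n = 3) in wild type buds and had 0 reads in silenced buds, at least 4755-fold lower. Bra038907, with a coding length of 360 bases, stood at 193 ± 4.90 CPM in wild type buds and had 0 reads in silenced buds, at least 3353-fold lower. Bra020643 had no reads in any stem library, and Bra038907 had 3 reads in 1 silenced stem library and none in the others. Among the rises, Bra040672, with a coding length of 249 bases, had 0 reads in wild type buds and 40.9 ± 3.06 CPM in silenced buds, at least 658-fold higher, while it stood at 21.7 ± 1.75 CPM in wild type stems and 19.2 ± 1.13 CPM in silenced stems. Bra036206, with a coding length of 2694 bases, had 0 reads in wild type buds and 7.58 ± 0.787 CPM in silenced buds, at least 122-fold higher. It also had 0 reads in wild type stems and 2.88 ± 0.865 CPM in silenced stems. All 4 passed edgeR's test in bud, with adjusted p-values of at most 1.65e-38.

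Genes restricted to bud were lowered at least 2-fold more often than other genes, while most of the genes that fell lay outside the class. This class, also chosen after the data were examined, held the 721 genes under 0.5 CPM in each of the 6 stem libraries and averaging at least 2 CPM over the 6 bud libraries of both genotypes. In silenced buds 370 of them, 51.3%, were called at least 2-fold lower and 125, 17.3%, at least 2-fold higher, and 76 were not called at any size. Falls of 8-fold or more were called for 247 genes of the class and rises of that size for 23. Among the other tested genes 23.1% were called at least 2-fold lower and 13.3% at least 2-fold higher. The summed level of the class went from 16720 ± 59.0 CPM in wild type buds to 10690 ± 62.9 CPM in silenced buds, a ratio of 0.639. As a set it fell relative to the other genes (limma's camera, adjusted p = 2.1e-05 with the preset correlation and adjusted p = 2.66e-05 with an estimated correlation). Here too the adjustment leaves out the classes and bins tried before, and the estimated correlation, 0.0011, rests on the spread between replicate libraries.

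Short genes tended to be lower and long genes higher in silenced buds. The fold change in bud correlated with coding length across genes (Spearman's rho 0.128), and the median log2 fold change was -0.30 in the fifth of genes with the shortest coding length, up to 609 bases, and 0.26 in the fifth with the longest, from 1794 bases. In stem the rho was -0.009. Counting changes of any size, 22439 genes, 79.8%, were called in bud, 10820 higher and 11619 lower, whereas limma called 11196 higher and 10565 lower on log2(FPKM + 1), and 10825 higher and 10341 lower on log2(FPKM + 0.1). Library totals alone in edgeR gave 11561 higher and 11038 lower.

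**Figure D2:**
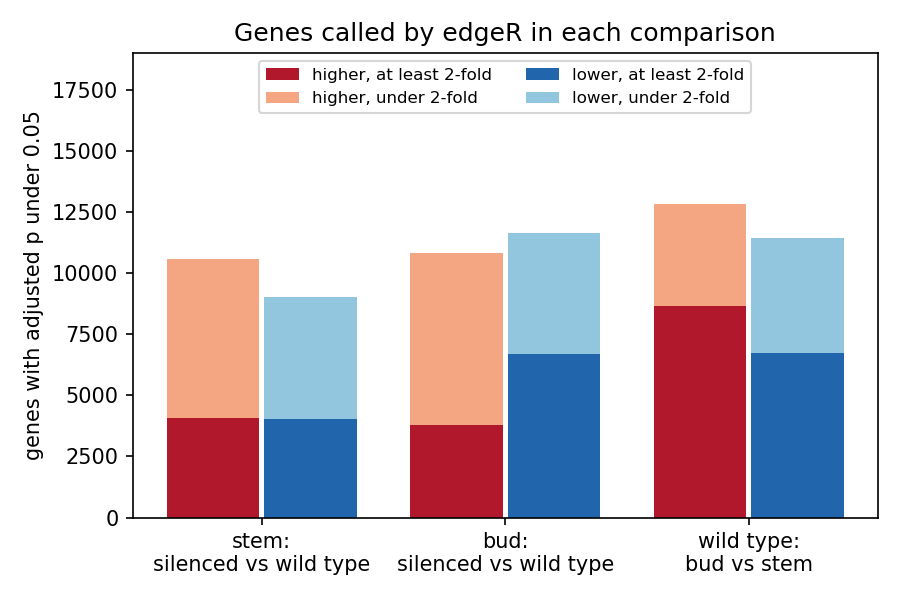
Number of genes with an edgeR adjusted p under 0.05 in each comparison of 3 libraries with 3, with higher genes in red and lower genes in blue; dark parts are changes of at least 2-fold. At least 2-fold changes were even in stem (4061 higher, 4025 lower) and leaned towards lower genes in silenced bud (3775 higher, 6683 lower).

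Setting both tissues side by side, many genes moved in opposite directions. Of the genes called in both tissues, 10517 had opposite signs and 5503 the same sign, so 65.7% were opposite. In 5842 genes levels were higher in silenced stems and lower in silenced buds, where independent lists would share 4371.7, with an odds ratio of 2.51 (95% interval 2.39 to 2.64, Fisher's exact test, two-sided). Another 4675 genes were lower in silenced stems and higher in silenced buds, against 3471.5 expected, with an odds ratio of 2.27. Without silenced bud replicate 1 these numbers were 5233 and 5257, so neither direction prevailed. Genes higher in both tissues numbered 2948 against 4071.1 expected, and genes lower in both numbered 2555 against 3727.8 expected. With at least 2-fold changes in both tissues, 1825 genes were higher in stem and lower in bud against 965.3 expected, whereas 1056 were lower in both against 956.8 expected (odds ratio 1.17, 95% interval 1.08 to 1.26). The fold changes of both tissues had a Spearman's rho of -0.221 and a Pearson's r of -0.018 across genes. The comparisons share no library. The opposite signs rest on the genotype labels of both tissues, which could not be checked on the level of BrCHR39. Genes are not independent, so these intervals describe the gene lists.

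**Figure D3:**
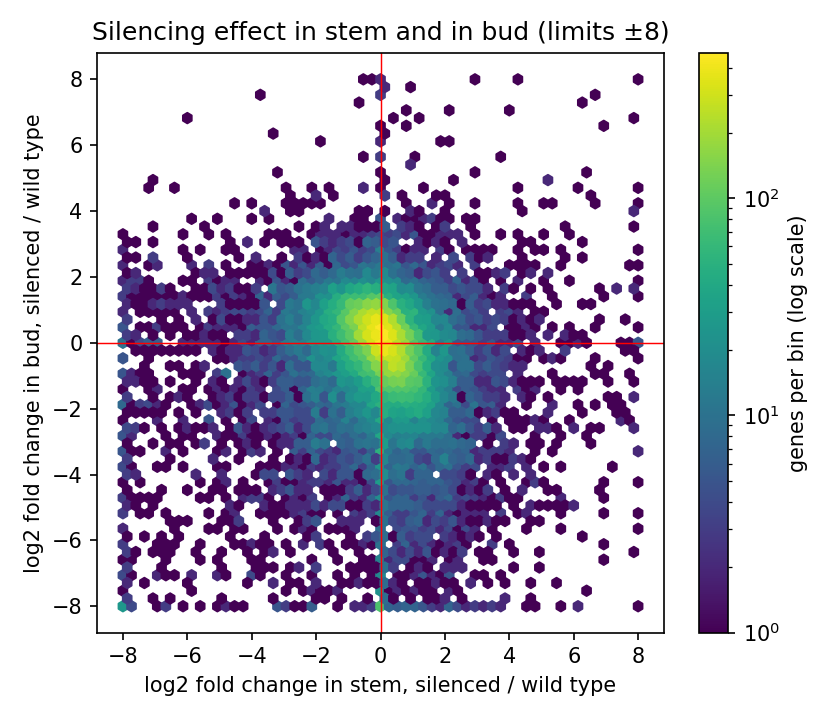
Log2 fold change of silenced against wild type plants in stem (x axis) and bud (y axis) for the 28114 tested genes, coloured by the number of genes per bin on a log scale; values beyond 8 in either direction are drawn at the limit. The dense centre tilts from upper left to lower right, and Spearman's rho across genes was -0.221.

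The difference between both effects was tested directly as an interaction. It was called for 20904 genes, of which 10922 had the more negative effect in bud and 9982 the more positive one (edgeR, 12 libraries); 13771 differed by at least 2-fold. This split turned without silenced bud replicate 1 (10104 more negative, 10647 more positive), without silenced bud replicate 3 (10136 and 10562), with limma on log2(FPKM + 1) (10989 and 11149) and with library totals alone (10399 and 10539). Genes with no reads in any library of 1 tissue could not be called, however large the effect in the other. Bra020643, lost in silenced buds and without reads in any stem library, is among these, so the counts leave out such losses. Bra033549 fell in stem, from 22.2 ± 1.2 CPM (SD, n = 3) to 0 reads, and rose in bud from 0.320 ± 0.106 to 2.72 ± 0.748 CPM. Bra028761 fell in stem from 235 ± 9.43 to 3.82 ± 0.553 CPM, whereas in bud it rose from 2 reads over 3 libraries to 5.58 ± 0.692 CPM. The reverse held for Bra038442, which rose in stem from 2 reads over 3 libraries to 18.6 ± 0.958 CPM and went in bud from 4.72 ± 1.44 CPM to 0 reads. Bra030523 rose in stem from 0.285 ± 0.248 to 20.4 ± 2.03 CPM and went in bud from 5.25 ± 0.528 CPM to 0 reads. For these 4 genes the interaction had adjusted p-values of at most 4.39e-51 by edgeR's quasi-likelihood test.

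Wild type buds and stems were compared to set the silencing effects against the difference between the tissues. In buds 8650 genes were at least 2-fold higher and 6736 at least 2-fold lower than in stems, so 54.7% of the tested genes differed by 2-fold or more, against 28.8% for silencing in stem and 37.2% for silencing in bud. Differences of any size were called for 24251 genes, 12827 higher and 11424 lower in bud (edgeR, 3 libraries against 3). Scaling by library totals alone shifted the bud to stem log2 fold changes by 0.37, which put 10440 of the called genes at least 2-fold higher and 5226 lower, and limma on log2(FPKM + 1) called 15080 genes higher and 8812 lower at any size. Bra008025, with a coding length of 633 bases, stood at 1386 ± 14.7 CPM in wild type buds and had 0 reads in wild type stems, at least 18050-fold higher in bud. Bra000129, with a coding length of 1365 bases, stood at 1137 ± 13.9 CPM in wild type buds against 0 reads in wild type stems, at least 14800-fold higher. In silenced buds Bra008025 stood at 2677 ± 5.46 CPM and Bra000129 at 505 ± 5.11 CPM. Bra013696, with a coding length of 300 bases, stood at 308 ± 9.97 CPM in wild type stems and had 0 reads in wild type buds, at least 4951-fold lower in bud, and Bra033034, with a coding length of 738 bases, stood at 303 ± 5.26 CPM in wild type stems against 0 reads, at least 4869-fold lower in bud.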

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

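The tests of regrouped libraries for stem, bud and tissue were chosen after the results were seen, and that for the interaction before. The silencing effect differed between bud and stem for 20904 genes by edgeR's interaction test. Of 40 splits of the libraries within tissues, drawn from 100 and the real one included, 1 reached that number. This shows only that the libraries group by genotype within tissues, which their correlations had already shown. Libraries correlated at 0.990 to 0.992 within groups and at most 0.893 between genotypes of a tissue. Mixed splits were therefore bound to call fewer genes, and the share decides nothing on the interaction itself. The splits mix genotypes within tissues, so they cannot tell a difference between both effects from a genotype effect that is equal in both tissues. Where the libraries of a group share 1 RNA pool, the splits set the genotype effect against technical spread only. The highest other split called 10349 genes. Swapping the genotype names in bud, counted as the same split, turns the interaction into a test of the sum of both effects and called 18785 genes. Of the other splits drawn, 5 called any gene, and all 5 kept the genotypes of 1 tissue whole and mixed those of the other. For stem, bud and wild type tissue the 10 possible splits are too few for a share under 0.05: the real splits called 19598, 22439 and 24251 genes, 1 of 10 each, and the highest other split called 0 in each.

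Genes called with opposite signs in stem and bud numbered 10517. Among the genes named for stem, Bra024251 rose in both tissues but by different amounts (edgeR's adjusted p of the difference 5.63e-33), and it stood at 16.1 CPM in wild type buds and 111 CPM in silenced buds. Bra005843 (3.59e-10) had 4 reads in wild type buds and 0 in silenced buds, and Bra034180 (0.00349) 36 and 1. Among those named for bud, the difference had an edgeR adjusted p of 5.49e-74 for Bra040672 and 3.7e-11 for Bra038907, the latter with 0 to 3 reads per stem library. For the genes named for opposite effects it was 4.39e-51 for Bra033549, 5.48e-86 for Bra028761, 1.92e-59 for Bra038442 and 2.08e-60 for Bra030523. Groups of 3 libraries are too small for a test of outlying samples.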

How the results depend on the processing

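All 16 named changes kept their sign and their call in each of their 260 values under the alternatives. They were picked as the largest called changes in these data, so this says nothing about the other genes. The class limits, the read minimum, library totals alone and upper-quartile scaling were chosen after the data were seen. Requiring at least 2-fold changes reduced the calls to 8086 in stem, 10458 in bud, 13771 for the interaction and 15386 between wild type tissues, and a test against 1.5-fold (glmTreat, added after the data were seen) gave 9881 in stem and 13404 in bud; both count fewer genes by construction. The other alternatives for these counts of calls stayed within 1.5 times the reported ones. Without each library in turn, calls ranged from 18852 to 18925 in stem, from 21898 to 22182 in bud, from 20573 to 20756 for the interaction and from 24089 to 24224 between tissues. The deviations of same-numbered libraries of different groups correlated at -0.015 to 0.012 (mean 0.0011) and no library correlated best with its own number throughout. The replicate numbers thus mark no shared signal. Libraries from 1 RNA pool could not show whether stems and buds came from the same plants. With the replicate block the calls were 19458, 22274, 20797 and 24147. The split of calls of any size turned in stem when the stem libraries were fitted alone (9109 higher, 9523 lower) and in bud with log2(FPKM + 1) (11196 higher, 10565 lower), log2(FPKM + 0.1) (10825 and 10341) and library totals alone (11561 and 11038). The split of same-sign calls, 2948 higher and 2555 lower as reported, turned with only the groups compared (2350 and 2425), DESeq2 (2563 and 2653), upper-quartile scaling (2568 and 2802), and without silenced bud replicate 1 (2541 and 2694) or 3 (2507 and 2668); the cause was not tested. Between tissues log2(FPKM + 1) called 15080 higher and 8812 lower. Opposite calls outnumbered same-sign calls under each alternative, from 9939 against 5138 with log2(FPKM + 0.1) to 10595 against 5370 with upper-quartile scaling. With class limits of 0.2 and 5 CPM, 113 of 206 bud-restricted genes were called at least 2-fold lower and 29 higher, and 53 of 117 stem-restricted genes lower and 25 higher; these narrower limits keep fewer genes. A fit of only the groups compared is the reported fit for the interaction. The planned tests of gene lists and of BrCHR39 were not run, because the identifiers could not be matched to names. Depth limits the folds of genes with 0 reads in a group, which are lower limits.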

Other observations

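The tests of fragments counted more than once, of 1 RNA pool, of a sequence or presence difference and of counting noise were chosen after the results were seen, and those of separate regulation, coding length and library scaling before; the trend on coding length had been seen by then, but not the ratio left after removing it. Complete loss of signal was more frequent than complete gain in silenced plants. Of genes with at least 100 reads over the 3 wild type stem libraries, 95 had 0 reads in silenced stems, whereas 22 genes with that many reads in silenced stems had 0 in wild type stems. In bud 151 genes were lost in this way and 6 gained.

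A small set was lost in both tissues. Of 18814 genes with at least 100 reads in wild type stems and in wild type buds, 29 had at most 3 reads in silenced stems and at most 3 in silenced buds, and 24 of these had 0 in all 6 silenced libraries; losses independent of each other would give 0.22. The minimum of 100 reads was settled after 50, 100 and 300 had been looked at: with 50 reads there were 51 genes and with 300 reads 9. The reverse, at least 100 reads in both silenced tissues and at most 3 in both wild type tissues, held for 1 of 18171 genes. This gene, Bra036206, had 106 reads over the silenced stem libraries and at least 23 in each. Leaving out any one of them thus had to take it below the minimum of 100, and the count was then 0. Without wild type bud replicate 1 the count was 2.

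The 29 genes had a median of 656 reads over the wild type libraries. This median follows from the minimum of 100 reads in each tissue and decides nothing on counting noise. The counts themselves, at least 100 reads in each wild type tissue against at most 3 in each silenced tissue at similar depth, argue against counting noise for these genes. A sequence or presence difference between the genomes of the silenced lines and the wild type plants, which would leave no reads in any tissue, stays open. The 29 genes outnumber the 18 that fell 8- to 32-fold in both tissues, but the 29 are the pattern itself and the range of falls is a single one, so this decides nothing. Losses independent between the tissues would give 0.22 such genes, and the 29 seen argue against that. Separate regulation that reaches the same genes in each tissue stays open. Of the 64 genes at the floor in silenced stems, 45.3% were also at the floor in silenced buds, between the limits set for either answer. A transcriptional shut-off of these genes by BrCHR39 silencing was not tested and stays open.

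The excess of falls in silenced buds was set against technical trends. Removing the trend of the log2 fold change on coding length left 6447 genes at least 2-fold lower and 3895 higher, a ratio of 1.66 against 1.77 before, which argues against coding length as the whole cause. Making 2-fold falls and rises equal in number among all tested genes, called or not, would need a shift of all log2 fold changes by 0.25. The scalings tried moved them by at most 0.069, which argues against the choice among these scalings as the cause. An error common to all of these scalings would not show in this comparison and was not tested. A bias of RNA quality or of library preparation unrelated to length, a different stage or makeup of the buds collected, and the silencing itself stay open, and none of these was tested.

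The spread between replicate libraries is small enough to matter for every p-value. In genes with 20 to 100 reads in a pair of libraries the variance was on average 1.52 times that of counting alone. Fragments counted more than once, such as both mates of a pair or copies from amplification, stay open as a source of this excess. In genes with over 2000 reads the coefficient of variation averaged 3.18%. That small spread is the pattern itself, so it decides nothing between 1 RNA pool behind the 3 libraries of a group and separate pools of many plants per library. The comparison with 1 RNA pool replaced a test of whether replicate numbers mark shared batches, after its mean correlation of 0.0011 had been seen.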
